A study of Homo sapiens with 15 samples.

How the data were processed

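The series holds droplet-based single-cell RNA sequencing of enzymatically dissociated skin biopsies from people with systemic sclerosis (SSc), an autoimmune disease with fibrosis of the skin. All 15 samples used here form 1 group, SSc skin, numbered as replicates 1 to 15. Per the labels, libraries were made with the 10x Genomics Single Cell 3' kit, version 2. Per the submitters' processing notes, base calls were converted with bcl2fastq, reads were aligned to GRCh38 and counted with Cell Ranger 3.0.2, and Seurat 2.3.4 was used downstream. The deposited values are unfiltered counts of unique molecular identifiers (UMIs, 1 per captured RNA molecule) for 33538 features in every barcode, with no normalization. No cell annotation from the authors was used here, so every cell name below was rebuilt from the counts, and a difference from the study may come from the rebuilt names.

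Cells were called per sample as barcodes with at least the larger of 500 UMIs and 10% of the 99th percentile of the top 3000 barcodes, at least 200 genes and at most 20% mitochondrial UMIs. This gave thresholds of 2577 to 5798 UMIs and 18829 barcodes. Doublets, droplets that hold more than 1 cell, were scored per sample with scrublet in scanpy 1.11.5. The top-scoring 0.8% per 1000 cells were removed, which took out 202 barcodes (1.07%) and left 18627 cells. Library totals ranged from 10225318 to 41968237 UMIs with a median of 22680532. Each sample kept 640 to 1936 cells, with sample medians of 5971 to 13918 UMIs and 1748 to 2854 genes per cell.

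All cells were clustered together without batch integration, on 2000 highly variable genes and 30 principal components. Myeloid cells were clustered again on 1000 genes and 20 components. Both steps used 15 nearest neighbours with shared-neighbour weights, values clipped at 10 after scaling, and the Leiden algorithm at resolution 1 for skin and 1.5 for myeloid cells with 10 iterations and seed 1. The versions were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.

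Clusters were named from marker lists, with a minimum name score of 0.3 for skin and 0.4 for myeloid clusters. Where none of the best list's markers led a myeloid cluster, a list with at least 0.7 of the best score and at least 3 of its markers among the leading genes took the name. A cluster with more markers of another list among its 10 leading genes stayed unnamed. Names mean that cells carry the markers of that class (macrophage-like, cDC2-like), and the shorter form is used below. cDC1 and cDC2 are the conventional dendritic cell types, pDC are plasmacytoid dendritic cells, and mo-DC are monocyte-derived dendritic cells. The markers were fixed, but this scoring rule and the clustering settings were settled over several rounds after clusters had been seen. The small FCN1 monocyte-or-mo-DC cluster of 18 cells scored 0.9236 on the FCGR3A macrophage list and 0.8168 on its own list, and took its name from its leading genes, which include S100A8 and S100A12. A cluster among the myeloid cells that scored 0.9565 on the plasma cell list (86 cells) was moved to the B or plasma class.

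Choices made before the data were examined were the cell calling, the markers, the gene lists, the comparisons with their tests, the rule for named genes and the first set of alternatives. Genes of the readout lists entered no clustering. Of the other genes, only those whose symbol has an even first hexadecimal digit in its MD5 sum could enter the myeloid clustering, besides markers. Tests between myeloid classes used only genes that had not entered that clustering and are not myeloid markers. Y-linked genes, XIST and TSIX were left out.

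For each comparison, counts were summed per sample and class over samples with at least 10 cells of each class, and at least 4 such samples were required. Sums were tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood method with TMM scaling, filterByExpr and the sample as a block, because both classes come from the same biopsies. Adjusted p is by Benjamini-Hochberg with a threshold of 0.05. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation. CPM, the usual depth-scaled unit, were taken over all UMIs of the summed class. Where a class held 0 UMIs of a gene, the fold was computed against a floor of 3 counts over the group, and where it held 1 to 3, the ratio has an exact 95% counting interval. Limits and intervals of this kind cover counting error only.

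The named genes of a comparison are the 12 with the largest positive and the 12 with the largest negative log2 fold change among genes past the threshold, with at least 50 CPM in the higher class and the same direction in at least 80% of the samples. Mitochondrial, ribosomal protein, immunoglobulin and hemoglobin genes were left out, as were genes over 10 times higher in another skin class. List members with the largest changes and the genes of the series title, FCGR3A and FCN1, were named besides. Some genes that the rule takes are not reported here. Positions are from GENCODE 29 on GRCh38, since the sources used here do not give the annotation release behind the counts. SOD2 and RGS5 each have more than 1 identifier in the files and were matched to the lists by symbol.

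The readout lists were interferon response, inflammatory cytokine and chemokine, profibrotic and growth factor, complement, lysosome and phagocytosis, lipid handling, iron and heme, MHC class II and costimulation, Fc receptor and innate sensing, dissociation stress, glycolysis and hypoxia, and fibroblast activation. Marker lists of other skin classes were tested where at least 3 members could be tested, which held only for suprabasal keratinocytes. Adipocyte and neutrophil lists were written later, for tests in the closing section. For another such test each cell of the FCN1 class was paired with a macrophage of its sample, at the least summed squared distance in log10 UMIs and mitochondrial share, and the comparison was run on sums of the pairs. Scores per sample and class are the mean log2 of CPM plus a pseudocount of 1 over a list. Relations between shares and scores used samples with at least 30 myeloid cells and 50 fibroblasts, with two-sided permutation tests of 100000 resamples.

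The test was tried on simulated data with 200 genes changed by known folds, 50 for each fold size, on the real samples' means and library sizes. For cDC2 against macrophage (1488 genes), 72% of genes changed by 1.5-fold, 94% at 2-fold, 100% at 4-fold and 100% at 8-fold were recovered, with 11 false calls. For the FCN1 class against macrophage (1280 genes) these were 24%, 66%, 98% and 100%, with 5 false calls. For cDC1 against cDC2 (1274 genes) they were 30%, 84%, 100% and 100%, with 6 false calls. For the CHIT1-led cluster against other macrophages (1448 genes) they were 2%, 16%, 86% and 98%, with 1 false call. The simulated classes were fixed beforehand and genes were drawn independently of each other. These false calls therefore do not measure errors between classes drawn by clustering.

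Alternatives planned from the start were DESeq2 1.42.0 size factors, the DESeq2 Wald test, no low-count filter, no replicate block, at least 20 cells per class, cells with at least 1000 UMIs in every sample, a 10% mitochondrial limit, no doublet removal, myeloid resolution halved or doubled, centring per sample, clustering on genes with even and odd digits alike, a pseudocount of 10, and leaving out each replicate. A minimum of 500 UMIs, comparisons with at least 3 cells of small classes, and relations between scores were added after seeing the data. Cell-level settings were repeated on cells with at least 1000 UMIs for the FCN1 comparison, also after seeing the data. Marker levels in barcodes of 10 to 100 UMIs were taken as the free RNA of each library. No barcode overlap above 0.62% was found over the 105 pairs of libraries, where the median was 0.19%.

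Control skin, measures of disease severity and the mapping of samples to patients were not used here. The comparison of FCGR3A macrophages with other macrophages was left out in the one setting with enough of them, because that setting changes 2 choices at once and the class's leading genes held no marker of its list.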

Results

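Single cells from 15 skin biopsies of people with systemic sclerosis were sequenced from the 3' ends of their RNA. The 15 samples form a single group, SSc skin, with no control skin and no measure of severity among the data used here. Each library held 10225318 to 41968237 UMIs in all, and 18627 cells were kept, 640 to 1936 per sample. The series title is about FCGR3A+ macrophages, FCN1+ monocyte-derived dendritic cells (mo-DC) and plasmacytoid dendritic cells (pDC) in severe skin disease. The comparisons here therefore describe which cells the biopsies held, which genes set the myeloid classes of the same biopsies apart, and whether myeloid shares moved with fibroblast and interferon scores. The design text of the series speaks of 12 patients and the labels do not tie the 15 samples to them, so some samples may come from 1 person and the p-values below measure only the spread between these samples.

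Keratinocytes and fibroblasts made up most of the cells. Suprabasal keratinocytes, the outer living layers of the epidermis, were 27.5% ± 12.3 of cells (mean and SD, n = 15 samples), fibroblasts 23.1% ± 13.6 and basal keratinocytes 18.5% ± 11.2. Pericytes or smooth muscle cells followed with 8.63% ± 4.91, vascular endothelial cells with 8.28% ± 4.48 and myeloid cells with 4.97% ± 2.40. The fibroblast share spanned 3.62% to 57.5% between samples, and the suprabasal share 3.41% to 46.2%. Fibroblast clusters were led by SFRP2 and COL1A1, by CCL19, CXCL12 and C3, by PLA2G2A, MYOC and APOD, by COCH and TNN, and by SFRP4, C1QTNF3 and COMP (273 cells). Hair follicle or sebaceous cells were 3.78% ± 1.49, T or NK cells 2.03% ± 2.36, sweat gland cells 1.19% ± 2.31, Schwann cells 0.552% ± 0.384, B or plasma cells 0.458% ± 1.42, melanocytes 0.455% ± 0.294, lymphatic endothelial cells 0.396% ± 0.336 and erythrocytes 0.101% ± 0.220. Replicate 11 alone gave 72 of the 86 B or plasma cells (0.092% ± 0.158 without it), and replicate 12 gave 60 of the 174 sweat gland cells (0.607% ± 0.45 without it). Erythrocytes were 0.054% ± 0.128 without replicate 9. No cluster took the name mast cell at this threshold. When every barcode with at least 1000 UMIs was kept, T or NK cells were 6.12% ± 3.74 and mast cells 0.399% ± 0.466, so both shares depended on the calling threshold.

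**Figure D1:**
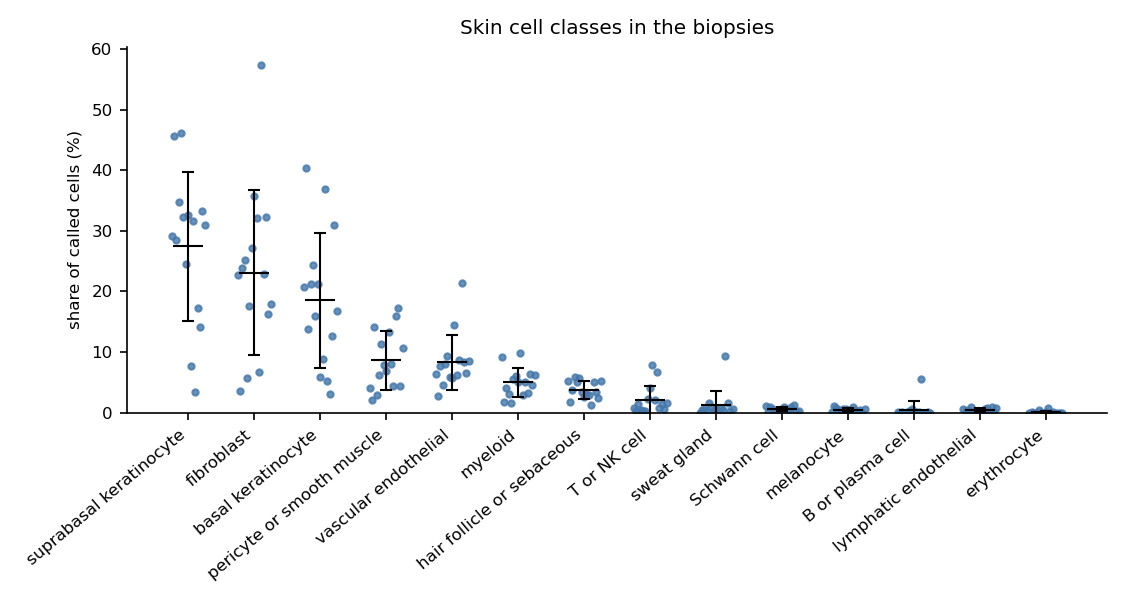
Share of called cells per skin class in percent, with 1 point per sample (n = 15) and bars for the mean and SD. Suprabasal keratinocytes (27.5%), fibroblasts (23.1%) and basal keratinocytes (18.5%) had the highest means, and samples spread widely within each of them.

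Fibroblast activation genes were mostly highest in fibroblasts, interferon response genes in vascular endothelium, and inflammatory genes in myeloid cells. Of 18 fibroblast activation genes that reached 20 CPM in any class ranked, 16 were highest in fibroblasts. Among them were the matrix proteins COMP (1860 ± 1331 CPM, SD, n = 15) and POSTN (1158 ± 752 CPM). The Wnt modulator SFRP2 (3482 ± 1481 CPM) and CTHRC1 (1074 ± 350 CPM) were too. The smooth muscle actin gene ACTA2 was highest in pericytes or smooth muscle (5238 ± 2254 CPM). Of 24 interferon response genes, 16 were highest in vascular endothelium, including IFI27 (3463 ± 903 CPM), IFIT1 (187 ± 164 CPM) and the antiviral GTPase MX1 (117 ± 77.4 CPM). Myeloid cells had the highest level of 16 of 22 inflammatory genes, such as IL1B (2757 ± 1344 CPM), the neutrophil attractant CXCL8 (7432 ± 3022 CPM) and CCL3 (2366 ± 1517 CPM), whereas IL6 (1516 ± 723 CPM) and CCL2 (6319 ± 2324 CPM) were highest in pericytes or smooth muscle. Myeloid cells also led for 13 of 14 MHC class II and costimulation genes and 9 of 10 Fc receptor and innate sensing genes, with HLA-DRB1 at 7446 ± 2756 CPM. Profibrotic and growth factor genes were spread, with 9 of 23 highest in myeloid cells, such as MMP9 (595 ± 324 CPM), and 6 in fibroblasts. Complement genes were divided, with 7 of 14 highest in fibroblasts, such as C3 (542 ± 284 CPM) and CFD (8896 ± 4445 CPM), and 6 in myeloid cells. The fibroblast activation score, a mean log2 CPM, was 6.51 ± 0.67 across samples. Ranks are among classes with at least 10 cells in at least 4 samples. This leaves out lymphatic endothelial cells, melanocytes, B or plasma cells and erythrocytes. Some ranks were near ties: CD55 was at 374.28 CPM in myeloid cells and 374.03 CPM in suprabasal keratinocytes. The ratio of the highest to the second class was 1.01 for CCL20, 1.02 for TNFAIP3 and 1.04 for ISG15. C1QA, C1QB and C1QC were macrophage markers and were not on the complement list. Dissociation stress genes were spread, with 7 of 16 highest in Schwann cells, 6 in pericytes or smooth muscle, 2 in myeloid cells and 1 in sweat gland cells. In myeloid cells the stress gene HSPA6 spanned 15.6 to 1708 CPM between samples. How far dissociation changed the inflammatory levels, here or between the myeloid classes below, was not tested. All these levels are descriptive, and no test was run between skin classes.

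Macrophages and cDC2, the dendritic cells that present antigen to CD4 T cells, were the main myeloid classes. Among 13 samples with at least 30 myeloid cells, cDC2 were 45.9% ± 11.8 of myeloid cells and macrophages 38.6% ± 14.8. The order turned with the calling, with macrophages at 44.7% and cDC2 at 35.9% at 1000 UMIs, and 43.4% and 28.6% at 500 UMIs. Cycling cells were 4.996% ± 4.41, the cross-presenting cDC1 4.38% ± 2.84, pDC 2.53% ± 3.89, FCN1 monocytes or mo-DC 1.79% ± 1.48 and mature dendritic cells 1.79% ± 2.37. The myeloid total was 887 cells here, or 1553 with at least 1000 UMIs, and the design text of the series names 2465 myeloid cells with 10 controls and 12 patients, a different set of samples. Macrophage clusters were led by RNASE1, CCL13, CCL18, CCL2 and SELENOP (179 cells), by IL10, CCL20 and CXCL3 (124 cells), and by CHI3L1, CHIT1 and FABP4 (35 cells). pDC numbered 21 cells, led by GZMB and LILRA4, and 7 of the 13 samples held none. Replicate 10 had the highest pDC share, and without it the mean was 1.63% ± 2.25 (n = 12). The pDC share was 1.64% with a 10% mitochondrial limit, where that library fell under 30 myeloid cells, 1.26% at 1000 UMIs and 1.47% at 500 UMIs. No cluster took the name Langerhans cell or FCGR3A macrophage, which does not exclude such cells inside other clusters. A cDC2 cluster of 128 cells scored 0.6652 on the Langerhans cell list and 0.8288 on the cDC2 list. HLA-DQB2, a marker on the Langerhans cell list, was among its leading genes. Its cells counted as cDC2 in the shares and comparisons here. A Langerhans cell cluster of 12 cells (1.71% ± 2.13 of myeloid cells, n = 13) appeared without doublet removal, and of 42 cells (3.20% ± 2.68, n = 15) at 1000 UMIs with the myeloid resolution doubled.

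FCGR3A, a gene of the series title, encodes the low-affinity IgG receptor CD16 (ENSG00000203747, chromosome 1, 161541759 to 161550737), and its near-identical neighbour FCGR3B makes its 3' counts uncertain. FCGR3A was at 108 ± 90.3 CPM in macrophages (SD, n = 14), 4.43 ± 5.61 CPM in cDC2 (n = 15), 19.5 ± 28.7 CPM in T or NK cells (n = 8) and 0.19 ± 0.48 CPM in fibroblasts. The 18 cells of the FCN1 class held 38 UMIs of FCGR3A, or 388 CPM when pooled. FCN1, also of the title, encodes ficolin-1, a lectin of blood monocytes (ENSG00000085265, chromosome 9, 134905890 to 134917963), and is a marker used to name its class. FCN1 reached 675 CPM in that class when pooled, 98.1 ± 59.3 CPM in macrophages (n = 14) and 72.3 ± 32.4 CPM in cDC2 (n = 15). Among macrophages, cDC2 and these 18 cells, both genes were thus highest in the 18 cells. With at least 1000 UMIs per cell the FCN1 class held 164 cells, 10.7% ± 3.69 of myeloid cells (n = 15), with FCN1 at 373 ± 256 CPM against 17.1 ± 31.6 CPM in macrophages (n = 6 and 14), and FCGR3A at 79.6 ± 49.7 CPM against 117 ± 107 CPM. Its size depended on the clustering. It took in 80 of the 338 macrophages called at the threshold set per sample (23.7%), 78 of them from the IL10-led cluster. Other settings at 1000 UMIs gave 42 to 169 cells, and no cells had this name without doublet removal or with centring per sample at the threshold set per sample. An FCGR3A macrophage cluster (125 cells, 7.25% ± 4.29 of myeloid cells) appeared only at 1000 UMIs without doublet removal.

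**Figure D2:**
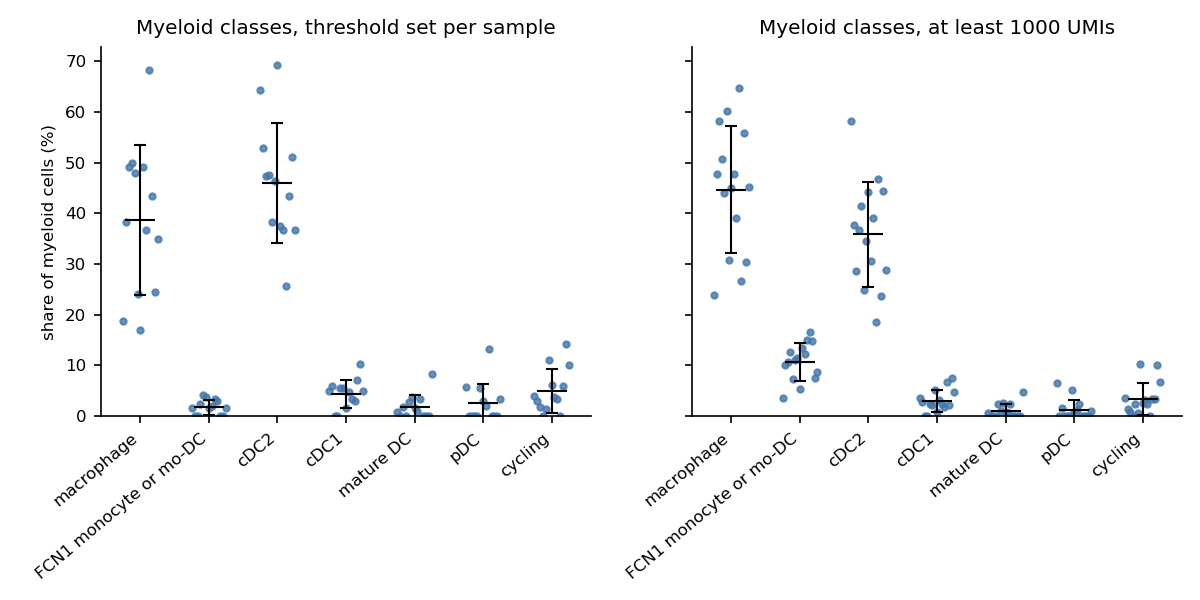
Share of myeloid cells per class in percent, with 1 point per sample and bars for the mean and SD, for cells over the threshold set per sample (left, n = 13 samples) and for cells with at least 1000 UMIs (right, n = 15 samples). Macrophages and cDC2 held most myeloid cells in both, while the FCN1 class went from 1.79% to 10.7%.

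The comparison of cDC2 with macrophages asked what sets the main antigen-presenting and scavenging cells of the same skin apart. Lysosome, lipid handling, iron and heme, and inflammatory genes were lower in cDC2 than in macrophages, and MHC class II genes were higher. SELENOP, the plasma selenium carrier (chromosome 5, 42799880 to 42887392), was 78.0-fold lower in cDC2, with a log2 fold change of -6.29 ± 0.44 (SE) and 34.8 ± 59.1 against 1941 ± 1086 CPM (SD, n = 14). CCL2, which draws in monocytes (chromosome 17, 34255218 to 34257203), was at 38.5 ± 39.95 against 1850 ± 1406 CPM (-5.47 ± 0.42). CST7, the cysteine protease inhibitor cystatin F (chromosome 20, 24949230 to 24959928), was 9.98-fold higher in cDC2, at 283 ± 143 against 30.5 ± 41.2 CPM (3.32 ± 0.32). HLA-DQB1, an MHC class II chain (chromosome 6, 32659467 to 32668383), was 2.55-fold higher, at 3667 ± 723 against 1521 ± 727 CPM. Of 1488 genes tested over 14 samples, 607 passed an adjusted p of 0.05 by the edgeR quasi-likelihood test, 299 higher and 308 lower in cDC2. For SELENOP and CST7 the edgeR quasi-likelihood adjusted p was 4.45e-10 and 3.88e-08, each with the same direction in 14 of 14 samples. Summed depth was 103520 to 953293 UMIs per sample for cDC2 and 63674 to 337227 for macrophages. Over all 15 samples the median cell had 8961.5 UMIs with 2.82% mitochondrial in cDC2 and 5688.5 UMIs with 3.65% in macrophages.

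Higher in cDC2 were LGALS2, a galectin (2.59 ± 0.25 on the log2 scale), ADAM8, a membrane metalloprotease (2.43 ± 0.30), and the receptor gene GPR157 (2.18 ± 0.32). CA2, a carbonic anhydrase, was 2.77-fold higher and CORO1A, an actin-binding coronin, 2.61-fold. The transcription factor RUNX3 (1.42), LIMD2 (1.42) and the septin SEPT6 (1.41) were higher too. HLA-DQA2 had a log2 fold change of 1.42 ± 0.27 but was higher in only 12 of 14 samples, and its counts are uncertain because it closely resembles HLA-DQA1. Lower in cDC2 were PLTP, which transfers phospholipids (-5.16 ± 0.33; 10.5 against 389 CPM), the cathepsins CTSD (-4.62 ± 0.28) and CTSL (-4.34), and GPNMB, a glycoprotein of lysosomes (-4.35 ± 0.33). The scavenger receptor STAB1 (-4.06), the lysosomal protease LGMN (-4.01) and the lysosomal membrane protein LAMP1 (-4.01) were also lower. So were the chemokines CCL4 (-4.02), CXCL1 (-3.97 ± 0.56) and CCL3 (-3.84), where CCL3 and CCL4 share reads with the copies CCL3L1 and CCL4L2.

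**Figure D3:**
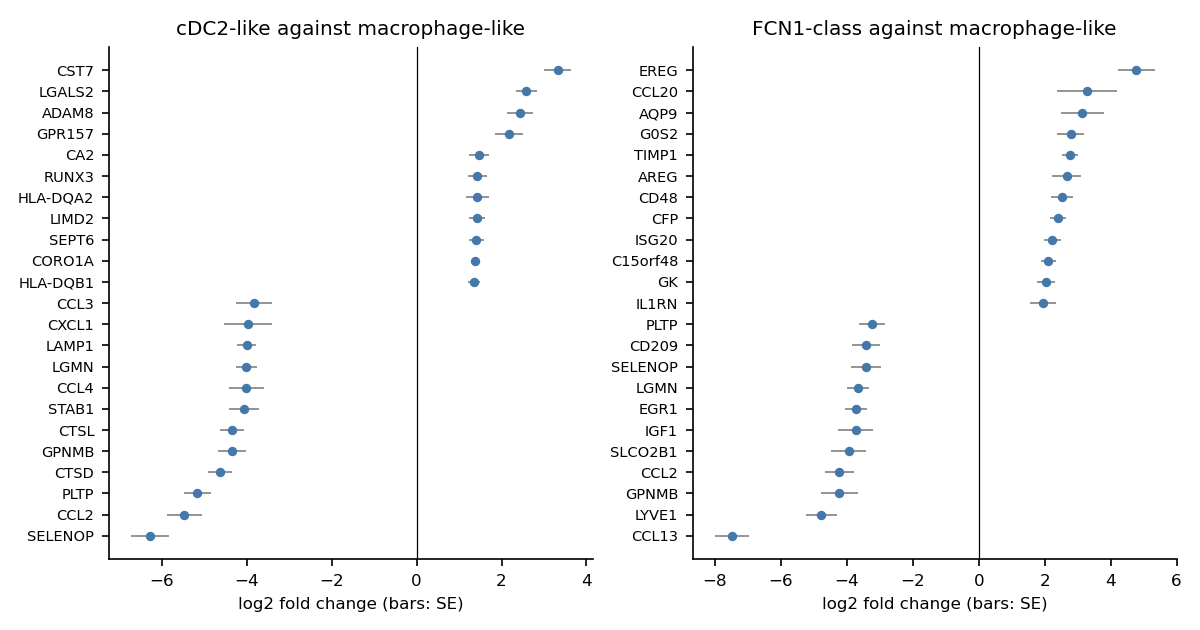
Log2 fold change with SE for genes named by the fixed rule, cDC2 against macrophages (left, 14 samples) and FCN1 class against macrophages (right, 6 samples, cells with at least 1000 UMIs). Positive values are higher in the class named first; SELENOP (-6.29) and EREG (4.78) are the extremes among genes with enough counts in both classes, CCL8 is left out because the FCN1 class held none, and the point for CCL13 rests on 2 UMIs in that class.

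All 16 lysosome and phagocytosis genes tested were lower in cDC2, also when adjusted over the list alone, for example LIPA (-2.98), CTSB (-2.33; 266 against 1382 CPM) and NPC2 (-2.08). The camera adjusted p was 2.61e-28, and adjusted p = 0.00125 with an estimated correlation. Of 17 inflammatory genes, 13 were lower (14 adjusted over the list alone) and 4 did not pass, with CXCL3 (-2.84; 854 against 5393 CPM), CXCL2 (-2.57), TNF (-1.68) and CXCL8 (-1.01) among the former and IL1B (-0.42) and EREG (-0.77) among the latter (camera adjusted p = 5.52e-13, and adjusted p = 0.00672 with an estimated correlation). IL1RN was lower here (-0.49), but it and EREG were higher in cDC2 with at least 1000 UMIs (0.76 and 1.56) and with at least 500 UMIs (0.79 and 1.30). At 1000 UMIs, 80 of the 338 macrophages called at the threshold set per sample fell in the FCN1 class and 20 in cDC2. Only 233 stayed macrophages. The cells compared thus differed, and whether this turned the 2 genes was not tested. The 20 came from the IL10-led cluster of 124 cells, named macrophage at a score of 0.4859, with 0.4119 on the FCGR3A macrophage list. Its leading genes include IL10, CXCL3, MMP19 and CXCL1, all lower in cDC2. In the iron and heme list 4 of 5 genes were lower (5 adjusted over the list alone), including the heme-degrading HMOX1 (-2.97 ± 0.41; 86.5 against 717 CPM) and the ferritin light chain FTL (-2.05), while the heavy chain FTH1 stood at -0.24 (camera adjusted p = 2.24e-06, and adjusted p = 0.0121 with an estimated correlation). In the lipid list 4 of 5 were lower (5 adjusted over the list alone), including the lipid droplet protein PLIN2 (-3.14; 72.8 against 666 CPM) and the cholesterol exporter ABCA1 (-2.59; camera adjusted p = 8.06e-06, and adjusted p = 0.0121 with an estimated correlation). Of 11 MHC class II and costimulation genes 9 were higher in cDC2, also adjusted over the list alone, such as HLA-DPB1 (1.13), the class II transactivator CIITA (0.90) and CD40 (0.88), while CD83 (0.13) and CD86 (0.42) did not pass (camera adjusted p = 8.20e-07, and adjusted p = 0.0196 with an estimated correlation).

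Of 12 profibrotic and growth factor genes, 9 were lower in cDC2 and 1 higher (9 and 2 adjusted over the list alone), with IL10 (-2.63; 33.9 against 261 CPM), the matrix proteases MMP19 (-2.38) and MMP9 (-1.52), and the EGF receptor ligand HBEGF (-1.84) lower and the protease inhibitor TIMP1 higher (0.79; 1651 against 845 CPM). The camera adjusted p was 0.00683, and adjusted p = 0.0242 with an estimated correlation. Of 16 dissociation stress genes 10 were lower and none higher (10 and 1 adjusted over the list alone), such as EGR1 (-2.33) and HSPA1B (-1.13), and the camera adjusted p = 0.00161 was lost with adjusted p = 0.270 with an estimated correlation. Of 5 Fc receptor and innate sensing genes 3 were lower, with FCGRT (-1.08) and LY96 (-1.51; camera adjusted p = 0.0334, and adjusted p = 0.0927 with an estimated correlation). Of 9 glycolysis and hypoxia genes 5 were higher and 1 lower (6 and 1 adjusted over the list alone), such as LDHA (0.80) and GAPDH (0.68) against the vasodilator peptide ADM (-1.19; camera adjusted p = 0.0540, and adjusted p = 0.158 with an estimated correlation). Of 6 complement genes 3 were lower, including C5AR1 (-2.66) and CFD (-2.69), and 2 higher, including properdin, CFP (1.35; camera adjusted p = 0.235, and adjusted p = 0.323 with an estimated correlation). None of 3 interferon response genes passed, with IFITM3 at 0.18, ISG15 at 0.04 and LY6E at 0.04 (camera adjusted p = 0.709, and adjusted p = 0.717 with an estimated correlation). Among 3 suprabasal keratinocyte markers 1 was lower (camera adjusted p = 0.345). With at least 20 cells of each class, in 7 samples, only 5 of 12 profibrotic genes and 3 of 16 dissociation stress genes were lower and 3 of 9 glycolysis genes higher. Without the sample block 6 of 16 stress genes were lower, and at 1000 UMIs 7 of 9 complement genes were. Without the low-count filter 10 of 25 interferon response genes were lower and 2 higher, and 14 of 23 profibrotic, 10 of 14 lipid, 8 of 10 iron and heme, 8 of 15 Fc receptor and 6 of 14 complement genes were lower. Profibrotic genes higher in cDC2 numbered 3 at 1000 and at 500 UMIs, with a 10% mitochondrial limit and with centring. Counts of lists for which none is given adjusted over the list alone were the same that way.

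**Figure D4:**
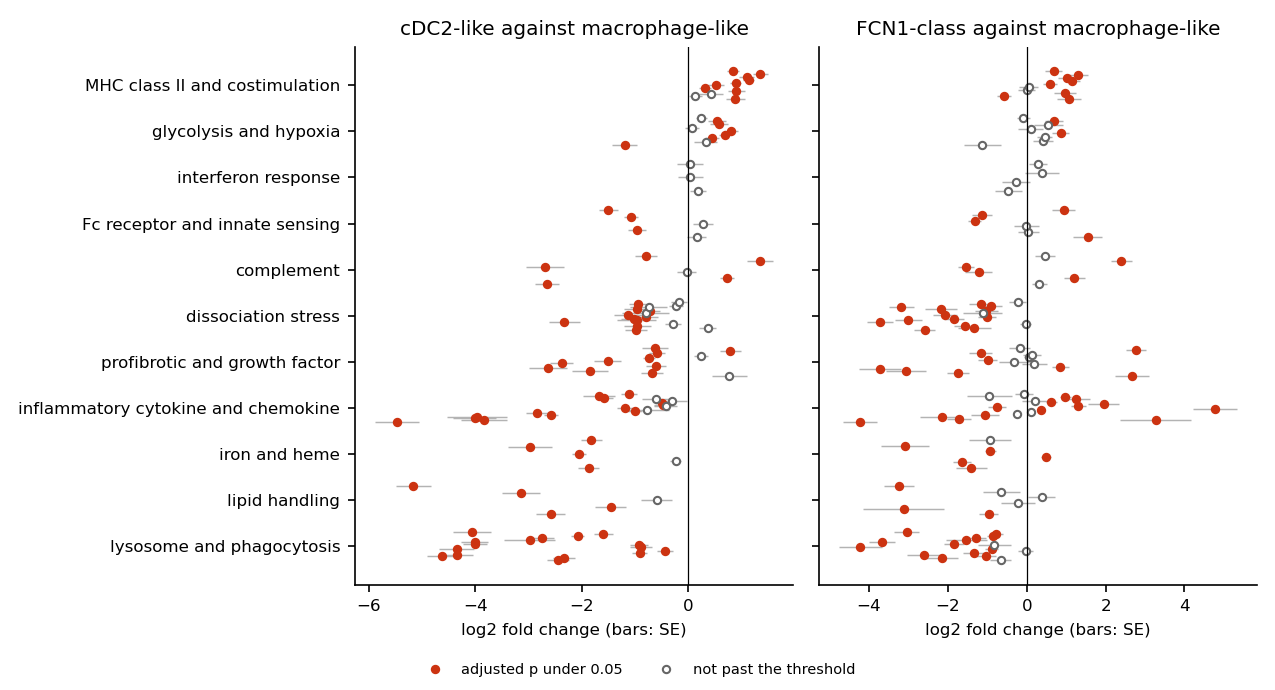
Log2 fold change with SE of each tested member of the fixed gene lists, cDC2 against macrophages (left, 14 samples) and FCN1 class against macrophages (right, 6 samples, cells with at least 1000 UMIs). Filled points passed an adjusted p of 0.05 by edgeR and open points did not, and all 16 lysosome genes lie below 0 on the left.

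The comparison of the FCN1 class with macrophages was planned because the title names FCN1+ monocyte-derived dendritic cells. Whether the class here holds those cells is not shown. Of its cells that were also called at the threshold set per sample, 80 had been macrophages, 18 the FCN1 class and 6 cDC2. The comparison could not be run for cells over the threshold set per sample, since no sample held 10 cells of both classes, and it is given for cells with at least 1000 UMIs in 6 samples, a calling that the design already listed. EREG, CCL20, G0S2 and TIMP1 were higher in the FCN1 class, and LYVE1, SELENOP, CCL2 and CCL8 were lower. EREG, the EGF receptor ligand epiregulin (chromosome 4, 74365143 to 74388751), was 27.4-fold higher, with a log2 fold change of 4.78 ± 0.56 (SE) and 607 ± 186 against 24.7 ± 34.6 CPM (SD, n = 6). CCL8, a monocyte chemokine (chromosome 17, 34319036 to 34321402), had 0 of 464650 UMIs in the FCN1 class and 528 of 1599373 in macrophages, at least 51.1-fold lower. For EREG the edgeR quasi-likelihood adjusted p was 0.000164, with the same direction in 6 of 6 samples. Of 1280 genes tested, 368 passed an adjusted p of 0.05, 196 higher and 172 lower. Summed depth was 54600 to 111434 UMIs per sample for the FCN1 class and 161606 to 456947 for macrophages. With a 10% mitochondrial limit 200 genes passed, and without doublet removal 203, each over 4 samples.

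Other genes higher in the FCN1 class were G0S2, an inhibitor of lipid breakdown (2.79 ± 0.41; 4296 ± 1275 against 799 ± 758 CPM), TIMP1 (2.77 ± 0.25; 2708 ± 1076 against 384 ± 86.4 CPM) and the channel gene AQP9 (3.14 ± 0.66). The chemokine CCL20 was higher in 5 of 6 samples (3.27 ± 0.91). AREG, another EGF receptor ligand, was 6.34-fold higher and properdin, CFP, 5.29-fold. The adhesion molecule CD48 (2.52), the exonuclease ISG20 (2.23), C15orf48 (2.11), glycerol kinase GK (2.05) and the IL-1 receptor antagonist IL1RN (1.95 ± 0.39) completed the list. CCL13 had 2 UMIs against 1240 in macrophages, a ratio of 180.1 (95% interval 49.8 to 1489). The hyaluronan receptor LYVE1 was lower (-4.78 ± 0.47; 6.74 against 256 CPM), as were GPNMB (-4.22), CCL2 (-4.22 ± 0.43; 186 ± 174 against 3704 ± 2595 CPM) and the transporter SLCO2B1 (-3.94). The growth factor IGF1 (-3.72), the immediate early gene EGR1 (-3.72), LGMN (-3.67), SELENOP (-3.42 ± 0.45), the lectin CD209 (-3.42) and PLTP (-3.24) were lower too.

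Most dissociation stress and lysosome genes were lower in the FCN1 class, but neither list passed with an estimated correlation. Cell quality moved with the class. Over all 15 samples the median cell had 4573.5 UMIs with 3.63% mitochondrial in the FCN1 class and 2859 UMIs with 4.8% in macrophages. In the 6 samples compared these were 3928.5 UMIs with 3.63% and 2627 UMIs with 4.71%. Of 16 dissociation stress genes 13 were lower (14 adjusted over the list alone), such as JUN (-3.18) and FOS (-3.00; 133 against 1123 CPM), with camera adjusted p = 2.55e-11, lost with adjusted p = 0.152 with an estimated correlation. Of 16 lysosome genes 13 were lower (14 adjusted over the list alone), such as STAB1 (-3.05) and CTSD (-2.61; 166 against 954 CPM), with camera adjusted p = 2.72e-10, lost with adjusted p = 0.137 with an estimated correlation. Of 6 iron and heme genes 4 were lower, including HMOX1 (-3.10; 250 against 2144 CPM), and FTH1 was higher (0.49), with camera adjusted p = 0.0171, lost with adjusted p = 0.3997 with an estimated correlation. Of 6 lipid genes 3 were lower, including APOE (-3.12 ± 1.02) and ABCA1 (-0.96), with camera adjusted p = 0.0412, lost with adjusted p = 0.541 with an estimated correlation. Of 5 lipid genes tested, 1 was lower with a 10% mitochondrial limit and 2 without doublet removal. Of 10 MHC class II and costimulation genes 7 were higher, including HLA-DQB1 (1.30), HLA-DPB1 (1.16) and CD40 (1.07), and CD83 was lower (-0.59), with camera adjusted p = 0.0171, lost with adjusted p = 0.581 with an estimated correlation. That MHC group depended on the cells. None of its 11 tested genes was higher past the threshold with a 10% mitochondrial limit or without doublet removal, and 4 of 10 were without the sample block and 4 of 15 without the low-count filter. With macrophages paired by UMIs and mitochondrial share, 3 of 8 were higher, with a median log2 fold change of 0.29.

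The other lists went both ways or did not pass. Of 18 inflammatory genes 8 were higher, including IL1B (1.31; 5002 against 2374 CPM), PTGS2 (1.24) and CXCL8 (0.36), and 5 were lower, including CCL4 (-2.16), CCL3 (-1.73) and CXCL1 (-1.06; camera adjusted p = 0.578, and adjusted p = 0.830 with an estimated correlation). Without the sample block 5 were higher and 2 lower, and 3 were lower both with a 10% mitochondrial limit and without doublet removal. With macrophages paired by UMIs and mitochondrial share, 4 of 15 inflammatory genes were higher and 6 lower, with a median log2 fold change of -0.08. Of 13 profibrotic and growth factor genes 3 were higher, including IL10 (0.85), and 5 lower, including HBEGF (-3.06) and GAS6 (-1.75; camera adjusted p = 0.734, and adjusted p = 0.830 with an estimated correlation). Of 6 complement genes 2 were higher, including CD55 (1.20), and 2 lower, including CFD (-1.54; camera adjusted p = 0.419, and adjusted p = 0.830 with an estimated correlation). Of 6 Fc receptor and innate sensing genes CLEC7A (1.55) and TLR2 (0.93) were higher and FCGRT (-1.32) and LY96 (-1.14) lower, with a median log2 fold change of 0.01 against a camera direction downwards (adjusted p = 0.734, and adjusted p = 0.830 with an estimated correlation). LDHA (0.86) and SLC2A3 (0.70) were higher among 8 glycolysis and hypoxia genes (camera adjusted p = 0.419, and adjusted p = 0.830 with an estimated correlation). None of 4 interferon response genes passed, with a median of 0.01 and a mean of -0.02 (camera adjusted p = 0.872, and adjusted p = 0.920 with an estimated correlation). Among 3 suprabasal keratinocyte markers 1 was lower (camera adjusted p = 0.146). Without the low-count filter 11 of 23 profibrotic, 7 of 14 lipid, 4 of 14 complement and 2 of 25 interferon genes were lower, and 0 of 14 glycolysis genes higher by edgeR. Without doublet removal 3 of 13 profibrotic genes were lower. With macrophages paired by UMIs and mitochondrial share, 0 of 6 profibrotic genes were lower and 1 was higher. Besides the dissociation stress and lysosome lists, the counts adjusted over the list alone equalled those over all genes tested.

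Of the 5 comparisons planned between myeloid classes, 4 could not be run on cells over the threshold set per sample. FCGR3A macrophages against other macrophages and Langerhans cells against cDC2 had no cluster under the first name. For FCGR3A macrophages this depended on the naming rule. The 18 cells named FCN1 monocyte or mo-DC scored 0.9236 on the FCGR3A macrophage list and 0.8168 on their own. pDC against cDC2 had 21 pDC and no sample with 10 of them. With at least 3 cells of each class at 500 UMIs, chosen after seeing the data, pDC differed from cDC2 in 327 of 940 genes over 4 samples by edgeR, 109 higher and 218 lower.

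No relation between myeloid shares and the fibroblast or interferon scores passed. FCN1 class and pDC shares were each set against fibroblast activation in fibroblasts and interferon response in fibroblasts and myeloid cells, a family of 6 relations over 13 samples. All samples together held 18 cells of the FCN1 class and 21 pDC, and 4 and 7 of the 13 samples held none. Shares from so few cells carry much counting error, so these results do not argue against a relation. The FCN1 share and fibroblast activation gave r = -0.351 (permutation p = 0.234) and rho = -0.354 (permutation p = 0.233), with r = -0.236 without the 2 samples farthest from the median share. The pDC share and fibroblast activation gave r = 0.342 (permutation p = 0.261) and rho = 0.233 (permutation p = 0.439), with r = -0.108 without those 2 samples. For the FCN1 share, the interferon score gave r = -0.113 and rho = -0.006 in fibroblasts (permutation p = 0.717 and 0.989; r = -0.36 without 2 samples), and r = 0.185 and rho = 0.281 in myeloid cells (permutation p = 0.539 and 0.347; r = -0.136 without 2 samples). For the pDC share, it gave r = -0.209 and rho = -0.042 in fibroblasts (permutation p = 0.477 and 0.896; r = 0.1 without 2 samples), and r = -0.322 and rho = -0.203 in myeloid cells (permutation p = 0.294 and 0.505; r = -0.052 without 2 samples). Benjamini-Hochberg adjusted p for r was 0.587 to 0.717 over the family, and the planned relations of FCGR3A macrophages had no cluster of that name to use.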

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

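The tests by swapped class labels, the test for neutrophils and the pairing of cells were chosen after the results they bear on had been seen, the last with its bounds set before it was run. The tests of summed depth and free RNA were not.

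Mast cells stood out among barcodes outside the comparisons. Of 111 mast cell-like cells with at least 1000 UMIs, 109 lay below the calling threshold set per sample, with a median of 1391 UMIs, in 14 of the 15 libraries. A cluster led by the B cell gene MS4A1 stood out in the same way, with 105 of 110 cells below that threshold and a median of 2411.5 UMIs, and replicate 6 gave 43.6% of it.

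Between cDC2 and macrophages, 607 of 1488 genes differed, with lysosomal and chemokine genes lower and MHC class II genes higher in cDC2. Exchanging the class labels within samples gave a count as large in 1 of 100 draws, the real one, and 0 genes in the highest other draw. The differences thus recurred across samples. Classes drawn by clustering on expression make that likely beforehand, so the swap cannot exclude a split made by the clustering. After both sums of each sample were thinned to the same total, 84.2% of the genes were called again in the same direction. This argues against unequal totals of the sums as the cause of most calls. Thinning sums leaves the UMIs per cell and the mitochondrial share as they were. Cells were not paired for this comparison, so depth and quality per cell stay open. For the median gene higher in macrophages, free RNA could give 2.51% of the level, which argues against free RNA for the set. No biological explanation was tested, since all samples are in 1 group, and the boundary between classes that clustering draws stays open. At 1000 UMIs, 20 of the 338 macrophages fell in cDC2.

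Between the FCN1 class and macrophages, 368 of 1280 genes differed, with EREG and G0S2 higher and CCL8 and LYVE1 lower. Exchanging labels within samples gave as many in 1 of 32 splits, the real one, with 0 in the highest other split. Here too the differences recurred across samples, but the swap cannot exclude a split made by the clustering. Samples that came from 1 person would also leave fewer independent splits. A candidate explanation is that the class, with S100A8 and AQP9 among its leading genes, holds neutrophils. HLA-DRB1 and HLA-DPB1 together stood at 143.9% of their macrophage level (9089 against 6315 CPM), which argues against a class made up wholly of neutrophils. The neutrophil markers written for this test were higher in the class, at 17.5 against 5.09 CPM, from 14 UMIs in each. A share of neutrophils therefore stays open. Free RNA could give 1.58% of the level of the median gene higher in the class. Each of the 108 cells of the class in the 6 samples compared was paired with a macrophage by UMIs and mitochondrial share (median 3928.5 and 3521.5 UMIs). The median of the 256 called genes still tested kept 83.9% of its log2 fold change, with quartiles of 65.5% and 101.4%. Leaving out each sample gave medians of 80.4% to 85.9%. Of these 256 genes, 255 kept their direction and 154 were called again. By list, 12 of 15 dissociation stress and 7 of 9 lysosome genes passed as lower. In the MHC class II list 3 of 8 genes were higher, and 0 of 6 profibrotic genes were lower. The kept folds argue against cell depth as the whole cause for the 256 as a set. Genes not called again and the other called genes stay open. No biological explanation was tested, and it stays open how far the lower stress and lysosome genes come from where clustering places the IL10-led macrophages.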

How the results depend on the processing

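The 500-UMI calling, all alternatives to the FCN1 comparison at 1000 UMIs, the cDC1 and CHIT1 comparisons, the relations between scores and leaving out libraries for shares were chosen after seeing the data. Of the values that answer a comparison, 522 stayed on their side under an alternative, 18 moved, 2 weakened and 14 changed sign. Of genes named and tested members of the lists 7384 values held, 378 no longer passed, 161 came to pass and 10 changed sign. Except where a reason is given, the cause was not tested.

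Genes past the threshold ranged over the alternatives from 428 to 1144 for cDC2 against macrophage (607), 200 to 493 for the FCN1 class (368), 285 to 706 for cDC1 against cDC2 (357) and 36 to 198 for the CHIT1-led cluster (158). Those over 1.5 times away were, for cDC2, 1144 without the low-count filter, which tests more genes, 1002 at 1000 UMIs and 997 at 500 UMIs. For the FCN1 class they were 200 with the 10% mitochondrial limit and 203 without doublet removal. Both had fewer samples and a class redrawn to 92 and 99 cells (164), and these 2 changes were not told apart. For cDC1 it was 706 without the filter. For the CHIT1-led cluster they were 36 with the 10% mitochondrial limit and 93 with resolution halved as well as doubled. Of the genes called for cDC2 and tested in both, 566 of 596 were called the same way at 1000 UMIs, and for the FCN1 class 170 of 347 with the 10% mitochondrial limit, with 1 and 0 called the opposite way. Leaving out each replicate gave 554 to 619 for cDC2, 270 to 340 for the FCN1 class, 296 to 332 for cDC1 and 39 to 219 for the CHIT1-led cluster, the latter 39 without replicate 6 and 51 without replicate 3. Without the replicate block the counts were 508, 260, 309 and 198, and 503 of the 607 cDC2 calls were shared.

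T or NK cells were 6.12% at 1000 UMIs and 5.71% at 500 UMIs (2.03%), and Schwann cells 0.996% and B or plasma cells 0.727% (0.458%) at 1000 UMIs. Erythrocytes were 0.06% at 500 UMIs (0.101%). The FCN1 class was 10.7% of myeloid cells at 1000 UMIs and 0.0% both without doublet removal and with centring, and cDC2 were 28.6% at 500 UMIs. pDC were 1.26% at 1000 UMIs, 1.47% at 500 UMIs and 1.64% with the 10% mitochondrial limit (2.53%), and mature dendritic cells 1.03% and 0.896% at 1000 and 500 UMIs (1.79%). At 500 UMIs cDC1 were 2.81% (4.38%) and cycling cells 3.197% (4.996%). Leaving out 1 replicate moved 4 shares over 1.5 times, B or plasma cells to 0.092% (replicate 11), sweat gland cells to 0.607% (replicate 12), erythrocytes to 0.054% (replicate 9) and pDC to 1.63% (replicate 10). In cDC2 against macrophage, EREG turned to 1.56 and 1.30 and IL1RN to 0.76 and 0.79 at 1000 and 500 UMIs, and IL1RN to 0.17 with centring. For the FCN1 class HLA-DPA1 turned to -0.0199 and -0.14, HLA-DRB1 to -0.11 and -0.17, with the 10% mitochondrial limit and without doublet removal, and HLA-DQA1 to -0.10.

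No relation of myeloid shares passed in any setting run. For the FCN1 share, r turned to 0.027 (interferon in fibroblasts, shares of cells other than keratinocytes), -0.136 (interferon in myeloid cells, without the 2 farthest samples), 0.073 and 0.015 (activation and interferon in fibroblasts, 1000 UMIs) and 0.002 (interferon in fibroblasts, 10% mitochondrial limit). For the pDC share it turned to -0.108 and 0.1 (without the 2 farthest), -0.001, 0.121 and 0.096 (1000 UMIs) and -0.017, 0.175 and 0.064 (10% mitochondrial limit). Without the 2 farthest samples the stress score of fibroblasts and myeloid cells turned to -0.172, and 2 relations weakened, interferon in fibroblasts and basal keratinocytes (0.522) and stress in basal keratinocytes and myeloid cells (0.473).

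Not run for too few cells were the FCN1 comparison with at least 20 cells, at 500 UMIs, and at 1000 UMIs with resolution doubled, centring or genes of even and odd digits. Simulated 2-fold changes were recovered for 94% of genes in the cDC2 comparison (14 samples), 84% for cDC1 (7), 66% for the FCN1 class (6) and 16% for the CHIT1-led cluster (4), where numbers of samples and cells differ together.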

Other observations

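All comparisons and relations in this part were chosen after the data had been seen, as were the tests by swapped class labels and without replicate 6. The tests of adipocytes, doublet scores and mixing with a skin class were set before their results, the last after the doublet score was known.

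cDC1, which present antigen from other cells on MHC class I, had more of the peptide transporters and less of the inflammatory set than cDC2. With at least 3 cells of each class in 7 samples, TAP1 was higher by 2.17 and TAP2 by 2.40 on the log2 scale (319 against 76.3 and 160 against 31.4 CPM). C1orf54 (chromosome 1, 150268200 to 150280916) was 14.2-fold higher (3.82 ± 0.23 SE; 590 against 39.8 CPM; edgeR quasi-likelihood adjusted p = 1.38e-08; 7 of 7 samples), and the phosphatase DUSP4 (3.23), the transcription factor MYC (2.78) and cyclin CCND1 (2.02) were higher too. ZEB2, a transcription factor of the monocyte and cDC2 lineage, had 0 UMIs in cDC1, at least 22.4-fold lower, as had SAMSN1 (at least 20.5-fold), the inflammasome protease CASP1 (at least 17.0-fold) and the inhibitory IgG receptor FCGR2B (at least 31.1-fold, with reads that related FCGR2 copies can share). IL1RN had 3 UMIs, a ratio of 27.0 (95% interval 9.2 to 131.3), and ALOX5AP of the leukotriene pathway 3 UMIs, a ratio of 21.0 (7.1 to 102.4). MMP9 (-4.75), the restriction factor IFITM3 (-4.43), CXCL3 (-4.30) and FCGR2A (-4.27) were lower. Each of these samples held only 3 to 6 cDC1. For the median gene higher in cDC1, free RNA could give 5.37% of the level. Suprabasal keratinocyte markers were at 1992 CPM in cDC1 against 475 CPM in cDC2. MYC (1080 CPM) and CCND1 (424 CPM) were higher in another skin class than in cDC1. Whether RNA of other cells added to these 2 genes was not tested. By edgeR, 357 of 1274 genes passed, 153 higher and 204 lower. Exchanging labels within samples gave as many in 1 of 64 splits, the real one, with 1 gene in the highest other split. The differences thus recurred across samples, but the swap cannot exclude a split made by the clustering that drew the classes.

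Of 11 inflammatory genes 8 were lower in cDC1, also adjusted over the list alone, with IL1B (-3.71; 168 against 1771 CPM), CXCL8 (-2.72) and CCL3 (-3.61) among them (camera adjusted p = 5.61e-08, and adjusted p = 0.0146 with an estimated correlation). MHC class II genes split, with HLA-DPB1 (0.70) and HLA-DPA1 (0.71) higher and the peptide-exchange chains HLA-DMA (-0.69) and HLA-DMB (-0.95) and CD40 (-0.93) lower (camera adjusted p = 0.903). Of 8 profibrotic and growth factor genes 3 were lower, including TIMP1 (-3.08; camera adjusted p = 0.00616, lost with adjusted p = 0.141 with an estimated correlation).

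A macrophage cluster led by CHIT1, the chitinase of lipid-laden macrophages (chromosome 1, 203212827 to 203273641), expressed genes of lipid uptake and storage. At 1000 UMIs it held 44 cells against 685 other macrophages, and 4 samples had at least 3 cells of both. LPL, which frees fatty acids from lipoproteins (chromosome 8, 19901717 to 19967259), was higher by 5.67 ± 0.73 on the log2 scale (595 ± 355 against 12.5 ± 22.5 CPM, SD; edgeR quasi-likelihood adjusted p = 0.00132; 4 of 4 samples). APOC1 (5.18), the fatty acid carrier FABP4 (4.71 ± 1.14), the sterol hydroxylase CYP27A1 (4.69), the lipid receptor TREM2 (4.65), lysosomal acid lipase LIPA (4.42), APOE (4.09), LGALS3 (3.40) and CD9 (3.36) were higher too. CCL2 (-4.62), IGF1 (-3.69), STAB1 (-3.42) and GAS6 (-3.04) were lower, as were LYVE1, with a ratio of 57.5 (95% interval 15.7 to 478.6), and the iron exporter SLC40A1, with a ratio of 76.9 (13.6 to 3062). FTL was higher (1.21; 78645 against 35825 CPM) and HMOX1 lower (-2.20). By edgeR, 158 of 1448 genes passed, 92 higher and 66 lower. Of 10 lipid handling genes 8 were higher (8 higher and 2 lower adjusted over the list alone), with camera adjusted p = 3.73e-11, lost with adjusted p = 0.0578 with an estimated correlation, and with a 10% mitochondrial limit 4 of 7 were higher. The cluster was picked after its leading genes, lipid genes among them, had been seen, so that list is no independent evidence.

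Replicate 6 gave 22 of the 44 cells of this cluster, and the count of genes passed went from 158 to 39 without it and to 51 without replicate 3. Of the called genes that could be tested without replicate 6, 30.2% were called again, 39 of 129, so it stays open how far they rest on that library. That test had 3 samples and 885 genes, so a loss of power could lower the count too. Among 8 lipid handling genes tested without replicate 6, 6 were higher and 0 lower. The cells could be doublets: their median doublet score lies at the 93.3 percentile of other macrophages, in the range that doublets would give, and their median depth was 8905.5 against 2757 UMIs. Adipocyte markers were at 0 CPM, and no named skin class held more than 9.8% of the genes higher in the cluster at its level (fibroblasts), which argues only against a partner among the named classes, so doublets stay open. Exchanging labels gave as many genes in 1 of 8 splits, with 0 in the highest other split against 158, and 8 splits are too few for a share under 0.05; no biological explanation was tested.

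Interferon response scores moved together in fibroblasts and myeloid cells across the 15 samples, with r = 0.762 (permutation p = 0.00131) and rho = 0.832 (permutation p = 0.00026), an adjusted p of 0.00786 for r and 0.00156 for rho over 6 relations, and r = 0.758 without the 2 farthest samples. Fibroblasts and basal keratinocytes gave r = 0.601 (permutation p = 0.0174) and rho = 0.539 (permutation p = 0.0412), with an adjusted p of 0.0348 for r and 0.0823 for rho. Without the 2 farthest samples r = 0.522 had an adjusted p of 0.180, while rho was 0.593 (permutation p = 0.036, adjusted p = 0.0788), so the relation stayed about as large but did not pass with 13 samples. Dissociation stress in basal keratinocytes and myeloid cells gave r = 0.657 (permutation p = 0.00793) and rho = 0.682 (permutation p = 0.00634), with an adjusted p of 0.0238 for r. Without the 2 farthest r = 0.473 had an adjusted p of 0.180 and rho was 0.582 (permutation p = 0.0394, adjusted p = 0.0788), which did not pass either. The other 3 relations did not pass: interferon in fibroblasts and endothelium (r = 0.335, rho = 0.354, permutation p = 0.222 and 0.194, adjusted p = 0.332, r = 0.269 without the 2 farthest), interferon and activation in fibroblasts (r = 0.241, rho = 0.246, permutation p = 0.390 and 0.376, adjusted p = 0.468, r = 0.454 without them) and stress in fibroblasts and myeloid cells (r = 0.122, rho = 0.036, permutation p = 0.670 and 0.904, adjusted p = 0.670, r = -0.172 without them). The labels name no batch, so no value within batches can be given.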
